A study of Mus musculus with 2 samples.

How the data were processed

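H3K4me3 was measured by ChIP-seq in heart tissue from pooled mouse embryos of embryonic day 14.5, of mixed sex and of strain B6NTac;B6NCrl/Lap, per the labels. The labels give 2 biological replicates, 1 library each, with a fragment size range of 300 to 500 bp, and both fall into 1 group. The authors deposited 4 peak lists on mm10: 1 for each replicate, 1 called on both replicates together (the pooled list) and 1 of replicated peaks derived from the other 3, per the records deposited with the samples. Those records list 1 more source file, of a kind not stated, for replicate 2 and for the pooled list than for replicate 1. The aligner, the peak caller, its thresholds and the rule that made a peak replicated are not given in the sources used here.

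The deposited lists are in narrowPeak format, per the records deposited with the samples. Their start, end and summit columns are positions in bp, as deposited by the authors. The signal value of each peak was computed by the authors' peak caller, and its scaling is not given in the sources used here; the plan called it fold enrichment, which the deposited records do not state, so it is named signal. The −log10 p and −log10 q of each peak were also deposited by the authors. The smallest −log10 p was 2.00 in replicate 1, 2.02 in replicate 2 and 2.01 in the pooled list. No read counts were used here, so the depth of each replicate is unknown and no counting error can be given for single peaks. Signal values were ranked and described within a list and were not compared between lists, apart from correlations across genes.

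Protein-coding genes (21938, with 93513 transcript starts) were taken from GENCODE M21 on the 21 main chromosomes. A gene was called marked when a peak overlapped the window of 1000 bp either side of any of its starts. Peaks lying at most 1000 bp apart were joined into domains, and the width of a gene was that of the widest domain touching a start window. The CpG observed to expected ratio in the window was computed from the GRCm38.p6 sequence, with the highest value over a gene's starts, and genes were classed as low below 0.35, high from 0.6 and intermediate between. Peaks were placed at a start of any GENCODE transcript within 1 kb, else in an exon, an intron or between genes. Backgrounds came from 20 shuffles of the peaks within their chromosomes.

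The comparisons, the 26 gene lists and the rule for naming genes were fixed before the data were examined. For each list the rule names the 4 marked members with the widest domains (6 for cardiac transcription factors and sarcomere genes) and up to 3 unmarked members in alphabetical order. It also names the genes at the 10 widest domains and the 5 peaks of highest signal, the 5 strongest peaks beyond 5 kb from a start, the 3 strongest peaks of each replicate absent from the other, and fixed pairs of genes. The lists cover cardiac transcription factors, sarcomere, calcium handling and ion channels, atrial, ventricular, endocardial, epicardial and fibroblast genes, signalling, congenital heart disease, metabolism, cell cycle and housekeeping, and, as markers of other cells that a dissected heart could hold, erythroid cells, macrophages and leukocytes, liver, lung and gut epithelium, skeletal muscle, neurons, and glia and neural crest. Polycomb targets, Hox genes, pluripotency and germ cell genes, and olfactory and vomeronasal receptors completed them. Of the list symbols 2 (Ahsp and Tf) were not found, 3 had 2 gene identifiers, and 28 genes were in more than 1 list. Results of lists that share genes are therefore not independent.

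The share of marked members of a list was compared with that of other protein-coding genes by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over the 26 lists. The median width of marked members was compared with other marked genes by a two-sided permutation test with 100000 resamples, whose smallest p is 1e-05, adjusted over the 23 lists with at least 5 marked members. A call means an adjusted p under 0.05. CpG classes and the X chromosome were compared by Fisher's exact test. Replicates gave means and SD with n = 2. Intervals of shares are 95% Clopper-Pearson intervals and cover counting error only. No test between groups was possible with 1 group.

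Alternatives were peaks with −log10 q of at least 5 or 10, windows of 500 and 2500 bp, the most 5′ start only, the pooled list, each replicate's own list, no joining or joining within 500 bp or 3000 bp, an overlap of at least 50% of the peak or of both peaks, the same number of top peaks per replicate, distances of 1 and 20 kb, and a background of the same CpG class. The plan named the Cochran-Mantel-Haenszel test for the last; its exact conditional form was used because the counts were small, with the share expected from the other genes of the members' classes. Alternatives added after the data were seen were a background without receptors, genes without shared peaks, and genes matched on CpG ratio and number of starts.

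The code was tested first, on simulated intervals for the overlaps and on lists drawn from the real genes, with their replicated peaks, for the list tests. Interval overlaps equalled those of bedtools. Of 200 random lists of 20 genes, 5.0% had an unadjusted p under 0.05 in the share test (21884 genes), 3.0% in the exact conditional test (21884 genes) and 4.5% in the width test (14683 genes). Lists of 20 with all members or 5 members marked were called in 100% of cases, and 50 lists widened by a factor of 1.5 or 2.0 had a p under 0.05 in 100% of cases. Peaks on sequences outside the main chromosomes (10 in the replicated list) were left out of the gene comparisons. Tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9 and bedtools 2.31.1.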

Results

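Trimethylation of lysine 4 of histone H3 (H3K4me3), a chromatin mark found at the starts of active and poised genes, was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in the hearts of mouse embryos at embryonic day 14.5. The design held 1 group with 2 biological replicates, each a pool of male and female embryos. Replicate 1 had 30155 peaks covering 35.2 Mb and replicate 2 had 31702 peaks covering 40.0 Mb. A list called on both replicates together held 32018 peaks, and the list of replicated peaks, used below unless another is named, held 25114 peaks with a median width of 1370 bp. The deposited lists carry no read counts, so the depth of each replicate is unknown. The design has no other tissue, stage or treatment to compare with, and every p-value below is across genes in these pools, not across conditions. All positions are on mm10, and genes are those of GENCODE M21. The signal value of a peak is the authors' own and is used only to rank and describe peaks within a list.

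The question the design allows is which genes carry the mark in the embryonic heart, and the genes that build heart muscle came first. All 24 cardiac transcription factors had a replicated peak within 1 kb of a transcript start, among them Nkx2-5, Gata4, Tbx20 and Hand2, regulators that specify the heart and its chambers. Of 30 sarcomere genes 28 were marked, including the myosin heavy chains Myh6 and Myh7, cardiac actin (Actc1) and cardiac troponin T (Tnnt2). Myom2, an M-band protein, and Xirp2, an actin-binding repeat protein, were not. Among calcium-handling and ion-channel genes 24 of 25 were marked, including the gap-junction protein Gja1, the sodium-calcium exchanger Slc8a1, phospholamban (Pln) and junctophilin (Jph2). The exception was Sln, which encodes sarcolipin, an atrial regulator of the calcium pump. All 14 ventricular genes were marked, and 13 of 15 atrial genes, with Sln and the dehydrogenase gene Dhrs9 unmarked. Across all 21938 protein-coding genes 14719 (67.1%) were marked, and the replicates taken alone gave 67.4% ± 0.583 (SD, n = 2). Of the marked genes 2753 (18.7%) shared every peak with another gene, so their peaks cannot be assigned to 1 gene. The sarcomere list exceeded other genes with an adjusted p of 0.00209 by Fisher's exact test, and the share was 91.7% ± 2.36 (SD, n = 2) over the replicates. The adjusted p by the same exact test was 0.000319 for cardiac transcription factors, 0.00156 for calcium handling and ion channels, 0.0101 for ventricular genes and 0.197 for atrial genes. Against genes of the same CpG class, a measure of how CpG-rich the start is, the cardiac transcription factors no longer stood apart (93.6% expected, adjusted exact p = 0.143) and the atrial genes did (63.2% expected, adjusted exact p = 0.0112). The sarcomere genes stood further apart (43.3% expected, adjusted exact p = 2.92e-12).

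All 22 endocardial and endothelial genes carried the mark, among them Nfatc1, which is needed for valve formation, the Notch ligand Dll4, the transcription factor Fli1 and the natriuretic peptide receptor Npr3. All 22 genes of fibroblasts, valves and smooth muscle were marked, including the growth-factor receptor Pdgfra and the mesenchymal regulators Prrx1, Sox9 and Twist1. Each of these lists exceeded other genes with an adjusted p of 0.000569 by Fisher's exact test. In the epicardial list 11 of 15 genes were marked, led by the regulators Wt1, Tcf21 and Tbx18, while the mesothelial genes Msln, Muc16 and Upk1b were not. The epicardial share of 73.3% was not separable from other genes (adjusted exact p = 0.816), and the replicates taken alone gave 80.0% ± 9.43 (SD, n = 2). All 30 genes of Notch, BMP and Wnt signalling were marked, including Smad7, Smad6, Id2 and Hes1 (adjusted exact p = 6.79e-05). Of 30 genes mutated in congenital heart disease 29 were marked, with Gata6 among them and the exception of Foxh1, a partner of Nodal signalling (adjusted exact p = 0.000386). The signalling list did not keep its call against genes of the same CpG class, of which 94.7% were expected to be marked (adjusted exact p = 0.143), while the congenital heart disease list kept it (85.5% expected, adjusted exact p = 0.0112).

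Energy metabolism and proliferation genes were marked without exception. The mark lay at all 32 genes of mitochondrial respiration (adjusted exact p = 3.56e-05), among them the ATP synthase genes Atp5b, Atp5a1 and Atp5c1. It lay at all 20 genes of fatty acid oxidation (adjusted exact p = 0.000834), including the carnitine transferase Cpt1a and the regulator Ppargc1a, and at all 21 of glycolysis (adjusted exact p = 0.000569), including Eno3, Hk1, Pkm and Gapdh. All 24 cell cycle genes were marked (adjusted exact p = 0.000319), with Ccnd2, Ccnd1, Mki67 and Plk1 among them, as were all 22 housekeeping genes (adjusted exact p = 0.000569) such as Ywhaz and Eef1a1. Of the mitochondrial genes 13 shared every peak with another gene, as Atp5a1 did with Haus1, so the peak cannot be assigned to either. The share among all marked genes was 18.7%. Cell cycle and housekeeping genes lost their calls against genes of the same CpG class, for which 95.4% and 96.5% were expected to be marked (adjusted exact p = 0.668 and 1). Respiration, fatty acid oxidation and glycolysis kept theirs against 88.7%, 85.7% and 82.3% expected (adjusted exact p = 0.00323, 0.0185 and 0.00323).

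Genes of blood, immune cells, liver and skeletal muscle were marked less often than other genes. Of 20 genes of macrophages and leukocytes only Cd14 and Coro1a were marked, while Adgre1, Aif1 and C1qa, markers of tissue macrophages, were not (adjusted exact p = 2.37e-06). The macrophage share was 10% in replicate 1 and 20% in replicate 2, that is, without replicate 1. In the liver list 3 of 19 genes were marked, and 2 of these shared the peak with a neighbour, Apoh with Prkca and Foxa3 with Sympk. Foxa1 had its own peak, and albumin (Alb), alpha-fetoprotein (Afp) and Ahsg were unmarked (adjusted exact p = 3.89e-05). Erythroid genes were marked at 6 of 17, with the regulators Tal1, Epor, Klf1 and Nfe2 marked and Alas2, Epb42 and Gata1 unmarked (adjusted exact p = 0.0108). Skeletal muscle genes were marked at 9 of 22, among them Pax3 and Pax7, which mark muscle progenitors, and not at Myf5, Cacna1s or Chrna1 (adjusted exact p = 0.0150). The marked Actn3 and Mylpf shared every peak with another gene. Of the 22 pluripotency and germ cell genes 6 were marked, including Klf4 and Esrrb, and Ddx4, Dppa5a and Mael were not (adjusted exact p = 0.000398). Olfactory and vomeronasal receptors, which are silent outside sensory tissue, were marked at 3 of 1466, namely Vmn1r4, Olfr94 and Olfr1033, with Vmn1r4 sharing its peak with Nt5c3; Olfr1, Olfr10 and Olfr1000 were among the unmarked. Against genes of the same CpG class the macrophage and skeletal muscle calls ended (adjusted exact p = 0.0824 and 0.399). Both shares were still lower, at 10% against 25.5% expected for macrophages and 40.9% against 49.2% for skeletal muscle. The erythroid difference turned positive, at 35.3% against 28.0% expected (adjusted exact p = 0.538). Liver genes, pluripotency and germ cell genes and receptors kept their calls against 31.6%, 66.1% and 18.4% expected (adjusted exact p = 0.0470, 2.65e-09 and 2.81e-118). The erythroid call also ended without genes that share a peak (adjusted exact p = 0.0525).

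Regulators of other lineages carried the mark although the tissue was heart. Of 35 developmental regulators known as Polycomb targets 34 were marked, including Pax6, Otx1, Gbx2 and Nkx6-2, which pattern the nervous system, and Lhx3, with a peak of 270 and 339 bp in the replicates' own lists, was not (adjusted exact p = 0.000139). Of 39 Hox genes 34 were marked, with Hoxb7, Hoxa2 and Hoxb2 among them, and Hoxb8, Hoxc11 and Hoxc12 among the unmarked (adjusted exact p = 0.00862). Neuronal genes were marked at 18 of 22, including Isl2, Gad1 and Neurog2 and excluding Dcx and Slc17a6 (adjusted exact p = 0.199). Genes of glia and neural crest were marked at 13 of 16, with Tfap2a, Ednrb, Ngfr and Foxd3 marked and Gfap and S100b unmarked (adjusted exact p = 0.318). Lung and gut epithelial genes were marked at 13 of 20, among them Nkx2-1, Foxa2, Shh and Sox2, but not Krt5, Krt7 or Scgb1a1 (adjusted exact p = 0.816). Against genes of the same CpG class the Hox share of 87.2% was below the 95.6% expected (adjusted exact p = 0.0463) and the Polycomb target share of 97.1% was level with the 97.8% expected (adjusted exact p = 0.634). The Hox call also ended with peaks of −log10 q of at least 10 (adjusted exact p = 0.370) and with the most 5′ start alone (adjusted exact p = 0.228), and the neuronal list passed in the pooled list (adjusted exact p = 0.0258).

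**Figure D1:**
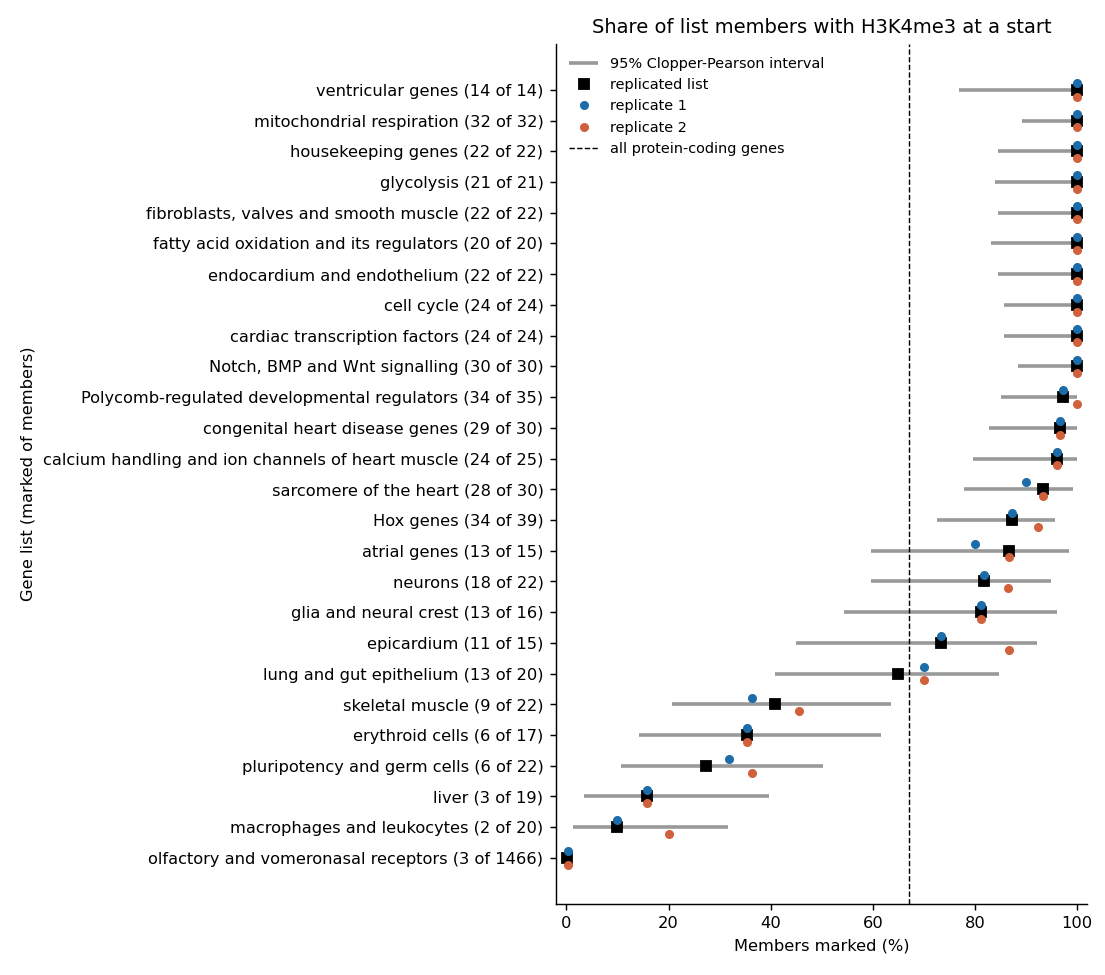
Percent of the members of each gene list with H3K4me3 within 1 kb of a transcript start, with 95% Clopper-Pearson intervals in grey, the replicated list as black squares, each replicate's own list as coloured points and the share of all protein-coding genes (67.1%) as a dashed line. Of the 26 lists 15 lay above other genes, from Hox genes at 87.2% to lists at 100%, and 6 lay below, from olfactory and vomeronasal receptors at 0.205% to skeletal muscle at 40.9%.

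Of the 10 widest stretches of H3K4me3 5 lay at genes of the cardiac transcription factor list, namely Hand2, Gata4, Nkx2-5, Tbx20 and Meis1. Peaks within 1 kb of each other were joined into domains, and the widest spanned 24.1 kb at Hand2, a regulator of the ventricles and outflow tract (chr8:57311895-57335983). It reached beyond the gene on both sides, over the starts of the non-coding gene Hand2os1, and measured 23.6 ± 0.588 kb (SD, n = 2) over the replicates. Next were Gata4 with 18.3 kb, the RNA-binding protein gene Qk with 17.8 kb, and Nkx2-5 with 17.7 kb (chr17:26835933-26853631; 18.1 ± 0.470 kb, SD, n = 2). The other 6 of the 10 widest domains lay at Meis2 with 17.3 kb, Tbx20 with 16.5 kb, Myh7 with 16.4 kb, Nfib with 14.8 kb, Meis1 with 14.2 kb and Tnrc18 with 13.7 kb. The Meis1 domain differed most between replicates in relation to its size, at 12.0 ± 3.21 kb (SD, n = 2). The median domain of a marked gene was 2165 bp.

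Cardiac transcription factors had the widest domains of any list, with a median of 6656.5 bp against 2163 bp for other marked genes, and all 24 members exceeded the overall median. The replicates gave a list median of 6792 ± 182 bp (SD, n = 2). Sarcomere genes followed at 5988 bp, with Actc1 at 11.1 kb, Tpm1 at 9.80 kb, Pln at 8.61 kb and Tnnt2 at 7.87 kb. Ventricular genes had a median of 5708.5 bp, with Myl2 at 7.75 kb, Hey2 at 7.63 kb and Fhl2 at 7.45 kb. The median was 4699.5 bp in the signalling list, led by Smad7 at 13.3 kb, and 4303.5 bp in the endothelial list, led by Nfatc1 at 8.87 kb. Glycolysis (4130 bp, Eno3 8.08 kb, sharing its peaks with Pfn1), congenital heart disease genes (4109 bp) and calcium handling and ion channels (3934 bp, Gja1 and Slc8a1 both 9.89 kb) also lay above other genes. The permutation test gave each of these 8 lists the smallest p that 100000 resamples allow (1e-05, adjusted 2.87e-05). Some lists share genes, so the 8 results are not independent. Myh7, for example, is a sarcomere and a ventricular gene, and Gata4 a cardiac transcription factor and a congenital heart disease gene. Fibroblast, valve and smooth muscle genes had a median of 3590 bp, led by Pdgfra at 8998 bp (adjusted permutation p = 5.11e-05). In the endothelial and fibroblast lists the excess over other genes was 2139.5 and 1426 bp, and 1289.5 and 866.5 bp without replicate 2. The fibroblast excess was 733.5 bp without joining of peaks and 753 bp with −log10 q of at least 10. The sarcomere excess of 3825 bp was 2528 bp without joining, and the cardiac transcription factor excess of 4493.5 bp was 7051 bp with joining within 3 kb.

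Smaller differences in width were found in other lists. Housekeeping genes had a median domain of 3104.5 bp (adjusted permutation p = 0.00339), with Ywhaz at 6.48 kb, and cell cycle genes 2900 bp (adjusted permutation p = 0.0110), with Ccnd2 at 7.99 kb and Ccnd1 at 6.41 kb. Polycomb targets had 2890 bp (adjusted permutation p = 0.00339), with Gbx2 at 4.95 kb (2868 bp in replicate 1). Hox genes were narrower, at 1559 bp (adjusted permutation p = 0.0110), as were skeletal muscle genes at 886 bp (adjusted permutation p = 0.0144), where Mylpf, at 3.49 kb, shared its peak with Sept1 and Tbc1d10b. Fatty acid oxidation genes reached 2732.5 bp (adjusted permutation p = 0.0594), with Cpt1a at 4.97 kb and Acaa2 at 4.86 kb. No difference was found for atrial genes (2631 bp, with Nr2f1 at 10.1 kb, 6532 bp in replicate 1, and Nr2f2 at 8.51 kb, 13097 bp in replicate 2), mitochondrial respiration (2471 bp), glia and neural crest (2425 bp), neurons (2145 bp), lung and gut epithelium (2046 bp), epicardium (1959 bp), pluripotency and germ cells (1923 bp) or erythroid cells (1472.5 bp), with adjusted permutation p from 0.187 to 0.936. The lists of macrophages, liver and receptors had fewer than 5 marked genes and were not tested. The excess of the Polycomb targets was 726 bp, 444 bp without replicate 2, and it ended without joining of peaks (8.5 bp, adjusted permutation p = 0.992), with joining within 500 bp (adjusted permutation p = 0.310) and with −log10 q of at least 10 (adjusted permutation p = 0.165). It was 459 bp within CpG classes and 2199 bp with joining within 3 kb, and turned negative against genes matched on CpG ratio and number of starts (−66 bp, adjusted permutation p = 0.790). The Hox difference ended in the pooled list (adjusted permutation p = 0.116), with joining within 3 kb (adjusted permutation p = 0.238) and without shared peaks (adjusted permutation p = 0.0592), and was −953 against −606 bp with matched genes. The skeletal muscle difference ended without replicate 2 (−695.5 against −1279 bp, adjusted permutation p = 0.104) and that of housekeeping genes without joining (adjusted permutation p = 0.0588), while its excess rose from 940.5 to 1472 bp with joining within 3 kb. Fatty acid oxidation genes passed under 6 of 13 alternatives, atrial genes under 5 and mitochondrial respiration under 1.

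**Figure D2:**
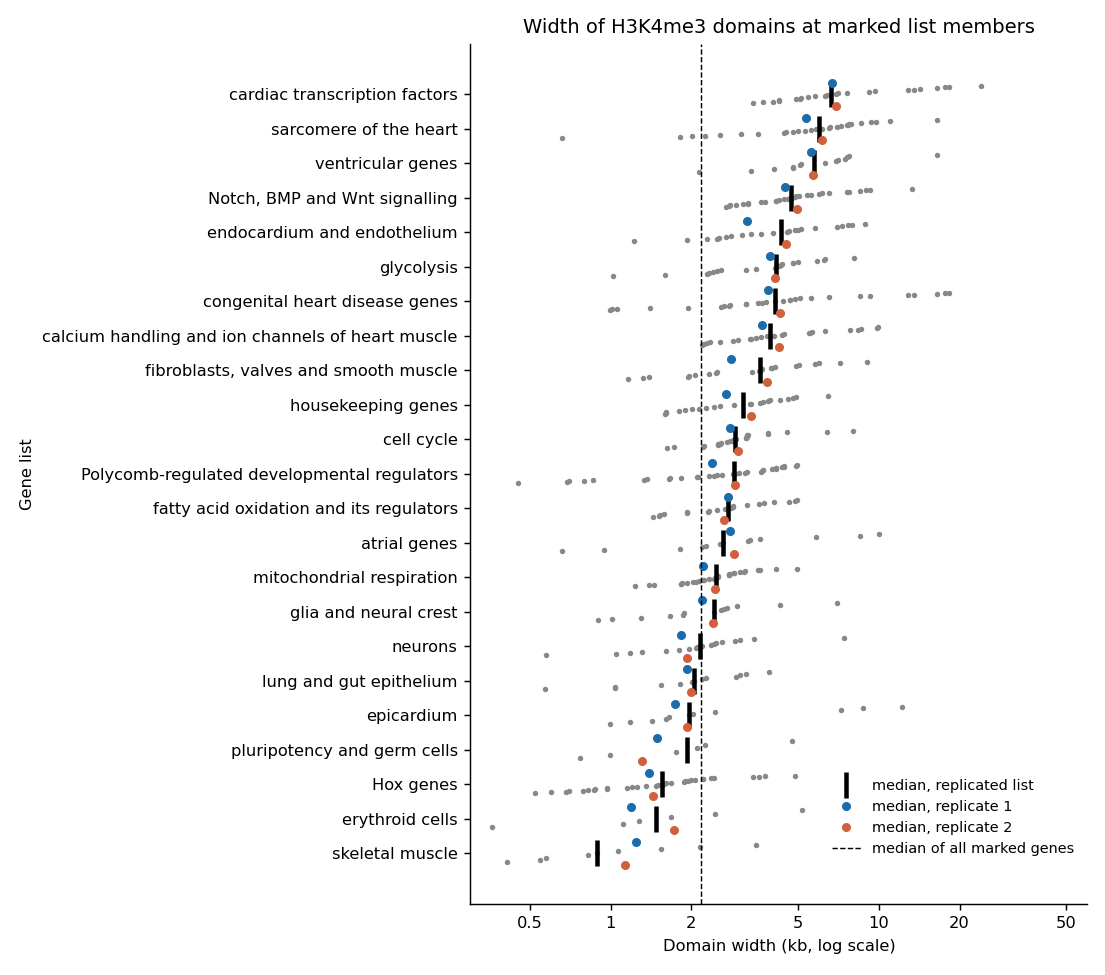
Width of the H3K4me3 domain in kb, on a log axis, of each marked member of a gene list (grey points), with the list median in the replicated list as a black bar and in each replicate as coloured points. The dashed line is the median of all marked genes (2165 bp); the list medians run from 886 bp for skeletal muscle to 6656.5 bp for cardiac transcription factors.

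Pairs of genes fixed in advance placed chamber genes side by side. The domain of Myh7, the slow myosin of the fetal ventricle, was 16.4 kb wide (15.6 ± 1.05 kb, SD, n = 2) and that of Myh6, the neighbouring fast myosin, 9.34 kb (8.67 ± 3.37 kb, SD, n = 2). Ventricular Myl2 had a domain of 7.75 kb (7.67 ± 0.0495 kb, SD, n = 2) and atrial Myl7 1 of 2.56 kb (2.42 ± 0.151 kb, SD, n = 2). The fetal troponin I gene Tnni1 had 6.97 kb (6.60 ± 0.530 kb, SD, n = 2) and the adult gene Tnni3 5 kb (4.43 ± 0.618 kb, SD, n = 2). Nppa, the atrial natriuretic peptide gene, had only 1.81 kb (1.57 ± 1.10 kb, SD, n = 2) with a signal of 4.43, and its neighbour Nppb 2.63 kb (2.56 ± 0.0403 kb, SD, n = 2) with a signal of 28.1. The difference between replicate means exceeded either SD in the pairs of Myh6, Myl2 and Tnni1, and not in that of Nppa, whose domain was 794 bp in replicate 1. The myogenic regulator Myod1 had a replicated peak of 544 bp with a signal of 4.41 that replicate 1 alone lacked, and Myog had none. Alb and Afp, the main secreted proteins of fetal liver, had no peak within 1 kb of a start, and a peak of 392 bp with a signal of 2.70 began 2000 bp after the start of Afp.

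**Figure D3:**
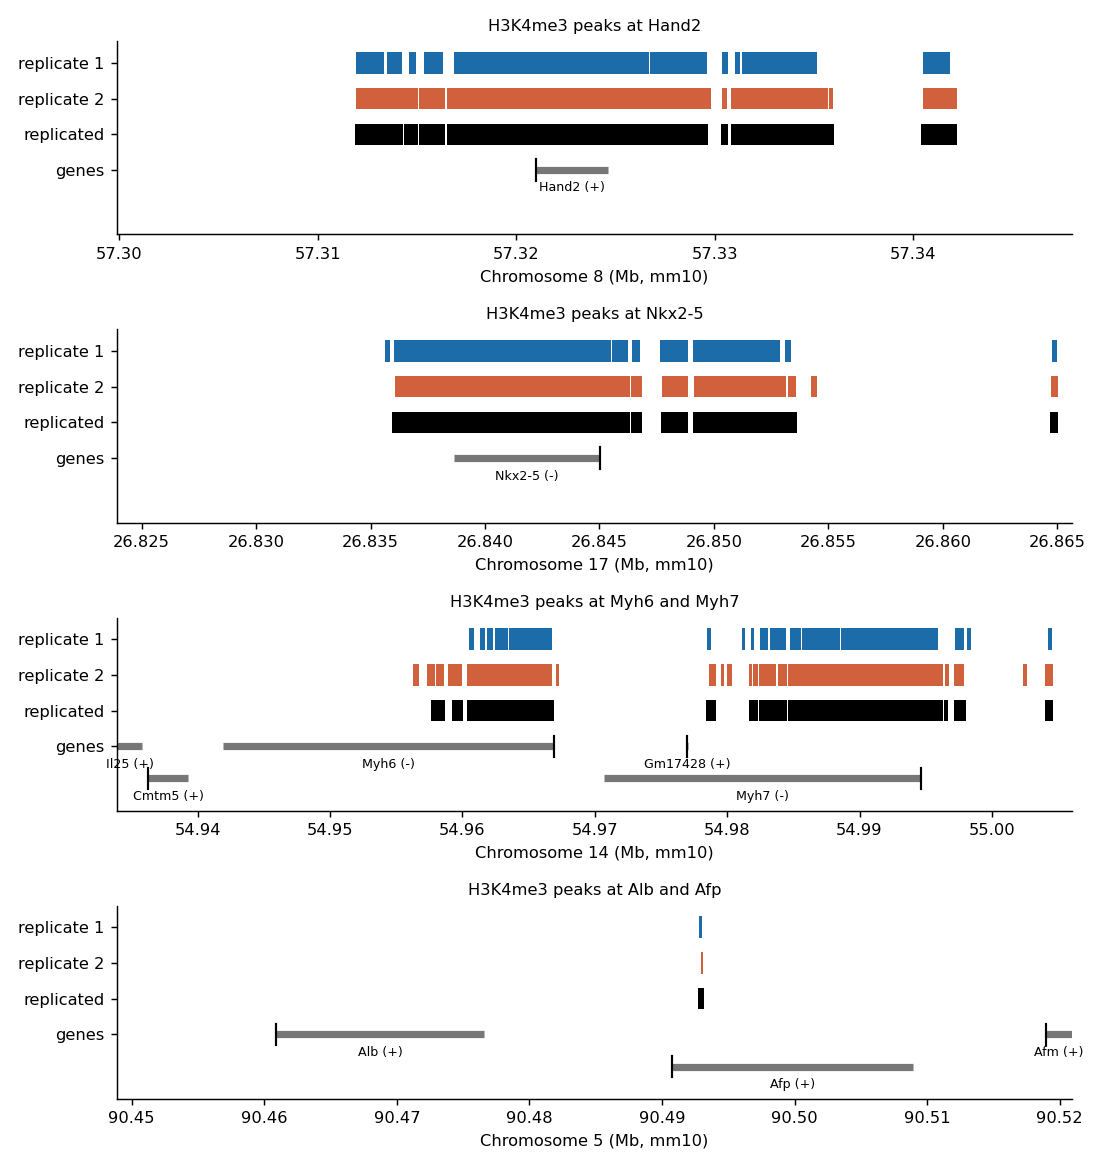
H3K4me3 peaks of replicate 1, replicate 2 and the replicated list along mm10 chromosomes 8, 17, 14 and 5 (position in Mb), with genes below and vertical ticks at their starts. Domains covered 24.1 kb at Hand2, 17.7 kb at Nkx2-5, 9.34 kb at Myh6 and 16.4 kb at Myh7, while Alb had no peak and Afp a single narrow peak of 392 bp inside the gene.

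The peak of highest signal in the replicated list was at Hsp90ab1, a cytosolic chaperone (chr17:45571467-45575029, signal 87.1). It was followed by the RNA-binding protein gene Khdrbs1 (86.6), the signalling adaptor gene Ywhaz (86.3), the divergent pair Rnf114 and Spata2 (85.7) and the ribosome biogenesis gene Wdr43 (85.5). The domain at Hand2 had a signal of at most 54.6 and that at Gata4 of at most 39.8, so the widest domains were not those of highest signal. Of the 25104 replicated peaks on the main chromosomes 16950 (67.5%) lay within 1 kb of an annotated start, against 10.6% of shuffled peaks. Peaks at starts had a median signal of 38.3 and a median width of 1833 bp. Introns held 13.8% of peaks (38.0% shuffled), exons 3.54% (2.86% shuffled) and the space between genes 15.2% (48.6% shuffled). The replicates' own lists had 60.9% ± 1.90 (SD, n = 2) of peaks at starts.

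CpG content divided marked from unmarked genes. Low-CpG genes with the mark included the sarcomere genes Myh7 and Actc1 and the erythroid genes Klf1 and Nfe2, and low-CpG genes without it included the heart genes Myom2, Xirp2 and Sln as well as Alb, Aif1 and Krt5. Of 8442 genes with a high CpG ratio 99.2% were marked, of 5903 intermediate genes 89.3% and of 7593 low genes 14.2%. The odds ratio between high and intermediate genes was 14.2 (Fisher's exact test, adjusted p = 1.24e-170). It was 712 between high and low genes and 50.2 between intermediate and low genes, with exact p-values below the smallest number the software represents. Domains were also wider with more CpG, at a median of 1205, 1729 and 2546 bp for low, intermediate and high genes. Without the olfactory and vomeronasal receptors 17.5% of 6145 low genes were marked. The low share depended on the window, at 35.0% with 2500 bp and 9.02% with 500 bp either side of the start, where the classes are drawn anew.

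Genes on the X chromosome were marked less often than autosomal genes. Unmarked X-linked genes of the lists included Alas2, Gata1 and Dcx. On the X chromosome 494 of 948 genes (52.1%) were marked, against 14221 of 20807 (68.3%) on autosomes, an odds ratio of 0.504 (Fisher's exact test, two-sided, p = 3.74e-24). The marked X-linked genes had a median signal of 29.0, against 46.2 for autosomal genes. On the Y chromosome 4 of 183 genes were marked, namely Ddx3y, Eif2s3y, Kdm5d and Uty, whose values were looked up after the count was seen.

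Peaks far from annotated starts were weaker than those at starts. The strongest was a peak between genes 17.5 kb from the protein-coding gene Fcgr4 (signal 65.8). Its nearest annotated start, that of Gm26110, was 8.5 kb away, and a RefSeq start was 2.42 kb away. Next was a peak in an intron (chr15:85669751-85673995, signal 62.0), whose nearest annotated start, that of Lncppara, was 16.1 kb away. The nearest protein-coding gene was Ppara, a regulator of fatty acid oxidation, with a start 61.0 kb away. Which gene holds the intron was not looked up. Then came a peak 45.5 kb from Larp1 (53.7), whose nearest annotated start, that of Gm26025, was 5.75 kb away. A peak 12.6 kb from Olfr1368 (51.9), with a RefSeq start 4.5 kb away, and a peak 5.58 kb from Shf (51.6) followed. The latter covered a start in RefSeq. In all 5283 replicated peaks (21.0%) lay more than 5 kb from any GENCODE start, with a median signal of 5.94 and a median width of 637 bp, 55.6% of them between genes and 37.7% in introns. The number was 8154 beyond 1 kb, 2086 beyond 20 kb, 8049 in the pooled list beyond 5 kb and 3360 with −log10 q of at least 10.

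The replicates were compared to see how well the peaks repeat. The domain at Hand2 measured 23224 and 24056 bp and that at Gata4 18281 and 18151 bp in replicates 1 and 2, while Qk measured 15138 and 17752 bp and Meis2 12459 and 17835 bp. Both replicates marked 14640 genes, 52 genes were marked by replicate 1 only and 233 by replicate 2 only; Upk1b, C1qa and Krt7 had a peak in replicate 2 alone and none in the replicated list. Across the 14640 genes the log2 signal of the replicates had a Pearson's r of 0.923 and a Spearman's rho of 0.843, and domain width had an r of 0.929 and a rho of 0.933. These are correlations across genes, which are not independent replicates. Of replicate 1 peaks 90.2% overlapped a replicate 2 peak, against 2.95% of shuffled peaks, and of replicate 2 peaks 78.9% overlapped a replicate 1 peak, against 2.77%. In the weakest decile of −log10 p the overlap was 58.2% for replicate 1 and 24.5% for replicate 2, and from the sixth decile upward it was 100% for both.

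**Figure D4:**
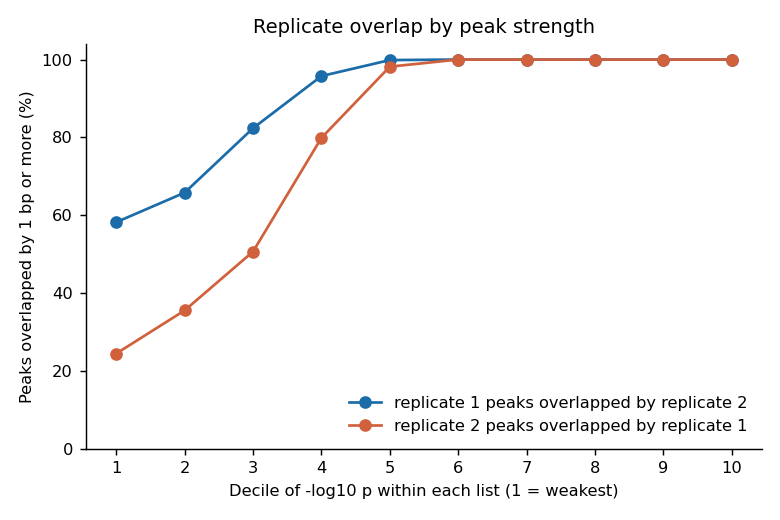
Percent of peaks of each replicate overlapped by a peak of the other by 1 bp or more, by decile of −log10 p within each list, from the weakest (1) to the strongest (10). Overlap rose from 58.2% (replicate 1) and 24.5% (replicate 2) in the weakest decile to 100% in the sixth and above.

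Peaks found in 1 replicate only were weak and narrow. The strongest of replicate 1 had Ido2 (signal 7.61), Calcrl (6.80) and Lcorl (6.80) as their nearest genes. The strongest of replicate 2 had Pdia4 (10.3), Tec (10.2) and Tex14 (9.38). All lay more than 5 kb from the named gene's start, from 5.3 kb for Ido2 to 586 kb for Lcorl. Replicate 1 had 2955 such peaks with a median signal of 3.40 and a median width of 234 bp, against 12.7 and 1037 bp for its shared peaks. Replicate 2 had 6698 with a median signal of 3.38 and a median width of 261 bp, against 22.4 and 1303 bp. Starts lay within 1 kb of 18.8% and 25.8% of them. The counts depended on the rule, at 8145 for replicate 1 when 50% of both peaks had to overlap. With both lists cut they were 475 and 3302 at −log10 q of at least 5, and 125 and 2403 at 10 or more. A peak was then also counted where its partner in the other replicate only missed the cut.

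The replicated list kept the stronger peaks of the pooled list. In all 25114 of 32018 pooled peaks (78.4%) were in it. The 6904 peaks left out had a median signal of 2.96, at most 5.76, a median width of 262 bp and a start within 1 kb for 23.6%, against a median signal of 22.2, 1370 bp and 67.5% for those kept. Of the peaks kept 23735 met a 50% overlap in both replicates, counted over either the kept peak or the replicate's peak. The other 1379 did not.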

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

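No test in this part was chosen after the result was seen. The replicated list held 10 peaks on 5 sequences outside the main chromosomes, a signal in data that the comparisons of the report did not use. They included a peak at the start of Vamp7, a vesicle fusion gene (signal 37.3), and a peak at the start of Tmlhe, an enzyme of carnitine synthesis (signal 26.4), both on the unplaced sequence GL456233. A peak with a signal of 26.4 lay at the start of CAAA01118383.1 on GL456216. There were no control samples to compare with, and neither a technical nor a biological explanation was tested.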

How the results depend on the processing

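Tests chosen only after the data were seen were those without receptor genes, without genes that share peaks, and with genes matched on CpG ratio and number of starts. No paired analysis was possible because the design has 1 group. Unknown depth limits what a missing peak means. The receptor list has no value against a background without receptor genes, and the width of pluripotency and germ cell genes none without shared peaks. Where no reason is given, the cause was not tested.

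Of 15 lists enriched for marked genes 9 kept their call under all 11 alternatives, as did 3 of 6 depleted lists, the receptors under 10; of 12 wider lists 10 kept it under all 13 alternatives and of 2 narrower lists 0. The X chromosome odds ratio lay between 0.489 and 0.516 under other thresholds, windows and lists, and at 0.745 within CpG classes. Against genes of the same CpG class the excess of marked members turned to 7.27 percentage points for erythroid cells, −0.608 for Polycomb targets and −8.45 for Hox genes, since CpG-poor genes are rarely marked (14 of 17 erythroid genes are CpG-poor) and CpG-rich genes nearly always. The number of enriched lists was then 10. Matched on CpG ratio and starts, the width excess of Polycomb targets turned to −66 bp. The number of narrower lists was 1 to 3 with either replicate left out, 1 with joining within 3000 bp and 1 without shared peaks.

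With −log10 q of at least 5, overlap was 97.7% (replicate 1) and 85.8% (replicate 2), peaks of 1 replicate only 475 and 3302, r 0.901, rho 0.831, the pooled share 97.2%, the start share 70.0%, peaks beyond 5 kb 19.8% and high-CpG genes 99.1%. With at least 10, these were 99.3%, 87.8%, 125, 2403, 0.878, 0.819, 99.96%, 76.1%, 16.1% (3360 peaks) and 99.0%, with 66.0% of genes, 12.3% of low and 87.7% of intermediate genes marked. Fewer peaks remained by construction. Both replicate lists were cut, so peaks of 1 replicate only also count those whose partner in the other missed the cut. Overlap was 86.5% and 71.9% by 50% of the peak, 73.0% and 69.4% by 50% of both peaks (8145 peaks of replicate 1 only), and 89.5% and 81.8% with equal numbers of top peaks. With a 500 bp window r was 0.919, the start share 65.5%, and low, intermediate and high genes were marked at 9.02%, 72.9% and 98.4%; with 2500 bp the start share was 73.2%, genes marked 68.1% and the classes 35.0%, 97.7% and 98.6%. With the most 5′ start 63.5% of genes were marked. The pooled list gave a start share of 58.0%, 25.1% beyond 5 kb (8049 peaks), 68.0% of genes and 15.7%, 90.4% and 99.3% of the classes. Beyond 1 kb lay 32.5% (8154 peaks) and beyond 20 kb 8.31% (2086 peaks). Leaving out either replicate gave a start share of 59.5% to 62.2%, 21.5% to 23.1% beyond 5 kb, 66.97% to 67.8% of genes, and low, intermediate and high classes of 13.9% to 15.3%, 89.2% to 90.3% and 99.2% to 99.3%.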

Other observations

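The tests of width against Polycomb targets and of signal within a CpG class were chosen only after the result was seen, as were the counts of Hox genes by position and of genes among the widest 5%; the shares within CpG classes of the lists and the widths without joining were planned, and the other tests were chosen after the pattern they address was seen but before their own values were.

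CpG-poor genes of some heart lists were marked more often than other CpG-poor genes. In the sarcomere list 17 of 19 CpG-poor genes were marked, including Myh7, Actc1, Myl2 and Tnnt2, a share of 89.5% against 14.02% of other CpG-poor genes (Fisher's exact p = 4.54e-13). In the endothelial list 7 of 7 were marked, 100% against 14.1% (Fisher's exact p = 1.15e-06), among them Cdh5, Pecam1 and Tie1, named after their values were seen. All 10 CpG-poor genes of the fibroblast, valve and smooth muscle list were marked, as were 4 of 6 atrial, 2 of 6 epicardial, 3 of 3 respiration and 3 of 3 glycolysis genes. Among the lists of other cells 3 of 9 lung and gut epithelial, 3 of 14 erythroid and 2 of 12 skeletal muscle genes were marked. None was marked of the 17 of macrophages and leukocytes, the 15 of liver, the 2 of neurons or the 3 of glia and neural crest. The general share of marked CpG-poor genes therefore does not account for the sarcomere and endothelial lists.

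The Hox genes carried marks of low signal in all 4 clusters. Their median width ran from 789 bp (Hoxc genes numbered 9 to 13) to 2209 bp (Hoxb genes numbered 1 to 8). Of the genes numbered 1 to 8, 21 of 23 were marked with a median signal of 13.6, and of those numbered 9 to 13, 13 of 16 with a median signal of 7.04. Of 24 cardiac transcription factors 19 were among the widest 5% of marked genes (at least 4874 bp), as were 18 of 28 sarcomere genes, 13 of 30 signalling genes, 9 of 14 ventricular genes and 2 of 34 Polycomb targets. No Hox gene was.

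The first pattern weighed is the width of domains at cardiac transcription factor and sarcomere genes. CpG-rich promoters with many annotated starts could widen domains, so marked genes were matched on CpG ratio and on the gene's own number of starts. The median excess was still 3954 bp for cardiac transcription factors and 4309.5 bp for sarcomere genes. Starts of other genes within a domain, as at Hand2, Tbx20 and Meis1, were not matched, so these values do not address them. Joining of neighbouring peaks could also widen domains. With each peak alone, however, the excess was 3377 and 2528 bp, each with the smallest permutation p possible (1e-05). Domains as wide at developmental regulators of other lineages are argued against, for Polycomb targets only, by an excess of 3766.5 bp over them (permutation p = 2e-05). The marks of those targets had a median signal of 18.7, against 43.7 for cardiac transcription factors. Regulators with marks of higher signal were not compared in this test, so it does not reach them. Lists not specific to the heart were wider as well (glycolysis 4130 bp, housekeeping 3104.5 bp, cell cycle 2900 bp), so whether width follows the identity of the tissue stays open; the same lists in another tissue would decide it, and no biological explanation was tested.

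The second pattern is the low share of marked genes in the lists of other cells. CpG-poor promoters are a candidate explanation. Within CpG classes the odds ratio was 1.79 for erythroid cells (exact p = 0.455) and 0.553 for skeletal muscle (exact p = 0.307). For erythroid cells no lower share was left within classes, at 35.3% against 28.0% expected. The explanation stays open for both lists, and a p that misses the threshold does not show equal shares. For liver the odds ratio was 0.00834 within classes (exact p = 0.0253, adjusted 0.0470) and 0.0918 without them. For macrophages and leukocytes it was 0.0648 within classes (exact p = 0.0476, adjusted 0.0824) and 0.0544 without them. The difference in shares shrank within classes, from −51.3 to −15.8 percentage points for liver and from −57.1 to −15.5 for macrophages. The test within classes argues against CpG-poor promoters as the whole cause for liver, and for macrophages only before adjustment. For liver this leans on 1 gene. Of the 16 unmarked liver genes 15 were CpG-poor, and the other was Afp, of the intermediate class. Whether the liver result holds without Afp was not tested. The adjusted p over all alternatives, of which this is the sole test within CpG classes, ran from 7.26e-06 to 0.0470 for liver and from 3.03e-07 to 0.0824 for macrophages. Marks called in another peak list but too weak for the replicated list are argued against as the main cause for all 4 gene lists. A peak in any list was found at 16.7% of the unmarked macrophage genes (3 of 18) and 7.69% of skeletal muscle genes (1 of 13). It was found at 0% of liver genes (0 of 16) and 0% of erythroid genes (0 of 11). Marks below the threshold of every list would look the same, and with the depth unknown they stay open. No biological explanation was tested.

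The third pattern is the low signal at marked genes of several lists of other lineages. Against marked genes of the same CpG class the median signal differed by −31.9 for Polycomb targets (18.7 against 50.7), −38.4 for Hox genes (9.09 against 47.5) and −27.8 for neurons (19.2 against 47.0), each with the smallest permutation p possible (1e-05, adjusted 7.67e-05). CpG class therefore does not account for it. The same comparison gave lower signal for lung and gut epithelium (adjusted permutation p = 0.000345), glia and neural crest (adjusted permutation p = 0.00092) and skeletal muscle (adjusted permutation p = 0.00115), of 23 lists tested. Erythroid cells (−5.49) and pluripotency and germ cells (−12.0) were not called (adjusted permutation p = 0.628 and 0.208). Some heart lists also ran lower without a call, among them epicardium (−15.0) and endothelium (−11.5), both with an adjusted permutation p of 0.103. Sarcomere, ventricular and calcium-handling genes ran higher without a call (11.7, 3.93 and 1.10). The mark may lie in a minority of cells or beside repressive marks, which 1 mark in whole tissue cannot separate, and no biological explanation was tested.

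Of the peaks more than 5 kb from a GENCODE start 9.50% lay within 1 kb of a RefSeq start (4.96% of shuffled peaks). Among the 406 strong ones, with a signal of 22.2 or more, 91 did. Starts known to RefSeq alone therefore do not account for most of these peaks. Within CpG classes the odds ratio of marked genes on the X chromosome against autosomes was 0.745 (exact p = 0.00194), between the bounds set. The marked share on the X chromosome was 15.7% against 14.4% for low, 80.5% against 90.0% for intermediate and 95.8% against 99.2% for high genes, so CpG class left a difference outside the low class. As 48.5% of X-linked genes were CpG-poor, against 33.5% of autosomal genes, how much of the lower share CpG-poor promoters account for cannot be told apart. The peak with the highest −log10 p in the pooled list (678), at Hjurp and Trpm8 (chr1:88275746-88278188), had a signal of 28.3, while the next 9 had at least 80.4.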
